A study of Mus musculus with 2 samples.

How the data were processed

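Bone marrow of C57BL/6 mice was grown with M-CSF, the growth factor that turns marrow precursors into macrophages, for 3 days and then given RANKL, the cytokine that drives macrophages into osteoclasts, for 2 days, per the labels' protocols. Poly-A RNA was made into libraries with an Illumina TruSeq kit. The series holds 2 libraries: 1 from wild-type (WT) cells and 1 from Foxo3 knockout (KO) cells, grouped by the genotype in the labels.

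The deposited values were read as FPKM, fragments per kilobase of transcript scaled to library size. No header or label names the unit. It was taken from the values: they are not whole numbers, the columns sum to 530701 in the WT and 540601 in the KO library, and the lowest values above 0 scale inversely with transcript length. Every value carries what appears to be an added constant of 0.000001, which was subtracted, so that a gene at the constant is one listed at 0. The submitters' processing notes name TopHat, edgeR and the mouse build mm10 without versions or roles. The quantifier, the annotation, any gene filter and any scaling between the libraries are not given in the sources used here. Counts were assumed possible when the tests were set out. Since the values are FPKM, the values as deposited were used, with no count model and no counting interval.

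Read totals are not given. Genes of a few reads hold whole multiples of what 1 read is worth, so their KO/WT ratios pile up at ratios of small whole numbers. Over 1661 genes above 0 and under 0.15 FPKM in both libraries, offsets were scored by how many ratios they placed within 0.015 (log2) of a ratio of numbers from 1 to 3. Matches to a ratio of 1 were given extra weight. The best offset gave a depth in the KO library 1.40 times that of the WT library, with no interval estimated. Low genes are therefore measured less finely in the WT library.

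The measure of each gene was log2(KO + 1) minus log2(WT + 1), with a pseudocount of 1 FPKM, called the log2 ratio throughout. It understates the difference of genes of low FPKM. A gene was measured where it reached 1 FPKM in at least 1 library, which held for 10003 of the 16614 genes listed. With 1 library per group there is no replicate check and no p-value, and a fixed rule of size took the place of a test: at least 2-fold on this scale.

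Before the data were examined, 27 gene lists with 696 entries were fixed, of which 669 were found in the files. File symbols were matched to the RefSeq gene table, 15706 directly, 814 through a single synonym and 94 not at all. The median log2 ratio of a list with 5 or more measured members was placed among 10000 random lists of the same size, matched on mean expression in 20 bins and drawn without the members. A list stood apart where its percentile was under 2.5 or over 97.5. This describes the 2 libraries. Genes of a pathway share regulation, so random lists understate how far a list can stray by chance.

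Genes were named by a rule fixed at the same time. It takes the FoxO genes, the 10 genes highest and the 10 lowest in log2 ratio among those at 10 FPKM or more in 1 library (unnamed models and small RNAs left out), the 3 members of each list with the largest absolute log2 ratio at that level (6 for the osteoclast and interferon-stimulated lists), the 3 most abundant members of each list of another cell type, and all sex-linked transcripts. Any other gene named was chosen after its values were seen, and the text says so. A few genes that the rule takes are not reported here. Coordinates come from GENCODE M21 on the mm10 assembly, and overlaps of exons were looked up without regard to strand, since strand use in counting is not given. The report names overlaps with named genes. Foxo1, Fdps, Ikbke, Irf1, Lilrb4, Plekhm1 and Pstpip2 overlap unnamed models or antisense transcripts, H2-L had no match in the annotation, and overlaps were not looked up for genes outside the rule.

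Alternatives fixed beforehand were trimmed-mean scaling (30% of log ratios trimmed from each end and 5% of mean levels), centring on the median gene, pseudocounts of 0.25 and 5, no minimum and a minimum of 10 FPKM, thresholds of 1.5-fold and 4-fold, the mean over list members, lists without their most changed member, and matching in 5 bins. Leaving out genes listed at 0, and removing lowess trends (span 0.3) on transcript length and GC content, were added after the data were seen. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and statsmodels 0.14.6, and plots used matplotlib 3.10.9.

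The steps were tested on simulated data built from the 9971 measured genes that lay below 2-fold in this comparison. Their log2 ratios were shuffled among genes of like expression. Few unchanged genes could pass 2-fold by this construction, so their count is no rate of false calls for the real comparison. The 2-fold rule called 98 of 100 genes changed 2.5-fold, 2 of 100 changed 1.5-fold and 1 of 9771 unchanged genes. The limit set for unchanged genes was first 0 and was relaxed after that 1 call was seen. Of lists with no shift 3 of 100 stood apart, as did 100 of 100 shifted by 0.2 (log2). These lists held random genes, so the share with no shift follows from the percentile bounds. It does not show how often an unchanged list of genes that share regulation would stand apart. The shift of 0.2 is larger than the absolute median of most lists that stood apart, and smaller shifts were not simulated.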

Results

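The series asked how loss of FoxO3, a forkhead transcription factor, bears on osteoclast formation, with an isoform of the gene named in its title. RNA was sequenced from mouse bone marrow macrophages after 2 days of RANKL, in 1 WT and 1 Foxo3 KO library. Both listed 16614 genes, with 6039 at 10 FPKM or more in the WT and 6033 in the KO library, and the KO library was 1.40 times as deep by the estimate from low genes. Across the 10003 measured genes the libraries correlated at r = 0.993 on the log2 scale, over genes that are not independent replicates. No value has a replicate error, so each difference describes these 2 libraries, not the genotypes.

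Foxo3 (chromosome 10, 42181841 to 42276755) stood at 10.3 FPKM in the WT and 0.548 FPKM in the KO library, 5.33% of the WT value and 18.8-fold lower, with a log2 ratio of -2.87. That ratio was -3.72 with a pseudocount of 0.25 and -1.46 with a pseudocount of 5. Gene-level values do not separate the isoforms or show which exons were lost. Of the related FoxO genes, Foxo1 read 4.96 FPKM in the WT and 5.15 FPKM in the KO library and Foxo4 read 8.58 and 7.14 FPKM. Foxo6 was not analysed here.

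Few genes differed by 2-fold: 12 were higher and 20 lower in the KO library. Of these, 5 higher and 14 lower genes reached 10 FPKM in 1 library. The counts include 1 higher gene listed at 0 in the WT and 2 lower genes listed at 0 in the KO library. Zinc finger models of chromosome 2, described further below, are also among the higher genes. Beside Foxo3, the lower genes at 10 FPKM or more included Slc40a1, the iron exporter ferroportin (chromosome 1, 45908068 to 45926523), at 59.9 FPKM in the WT and 22.4 FPKM in the KO library (log2 ratio -1.38), and Cd36, a scavenger receptor for lipids (chromosome 5, 17781690 to 17888801), at 84.7 and 31.9 FPKM (-1.38). The stress-induced transcription factor Atf3 stood at 16.5 and 6.72 FPKM, the chemokine gene Ccl3 at 17.6 and 7.42 FPKM and Wfdc17 at 121.9 and 53.4 FPKM, and Ypel3 in the KO library was at 44.0% of its WT value. Cnrip1 had a log2 ratio of -1.49, and its exons overlap those of Plek, so reads of the pair may not be separable.

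Among the higher genes, Slc6a12, a betaine and GABA transporter (chromosome 6, 121343076 to 121365775), read 6.07 FPKM in the WT and 15.7 FPKM in the KO library, a log2 ratio of 1.24. Scand1, which overlaps Cnbd2, read 8.05 and 25.2 FPKM. A further 6 of the same ranking lay below 2-fold: Ifitm1 (0.85), Colec12 (0.78), Mpp7 (0.76), the fatty acid desaturase Scd2 (0.74), H2-M2 (0.69), of a gene family with similar copies, and Mrps6 (0.66), which overlaps Slc5a3. Actr3, a subunit of the Arp2/3 actin complex, was listed at 0 in the WT and at 434 FPKM in the KO library. Adcy7, an adenylate cyclase, was listed at 38.2 FPKM in the WT and at 0 in the KO library, and no fold is given for either. Counts depended on the scale: with a pseudocount of 5 they were 5 higher and 6 lower, and with a pseudocount of 0.25 the lower count was 39. Of all measured genes, 97.8% had a log2 ratio within 0.5 of 0. The ratio was above 0 for 57.6% of them, with a median of 0.0253, and for 50.3% after trimmed-mean scaling. Counts of higher and lower list members below are to be read against that share.

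**Figure D1:**
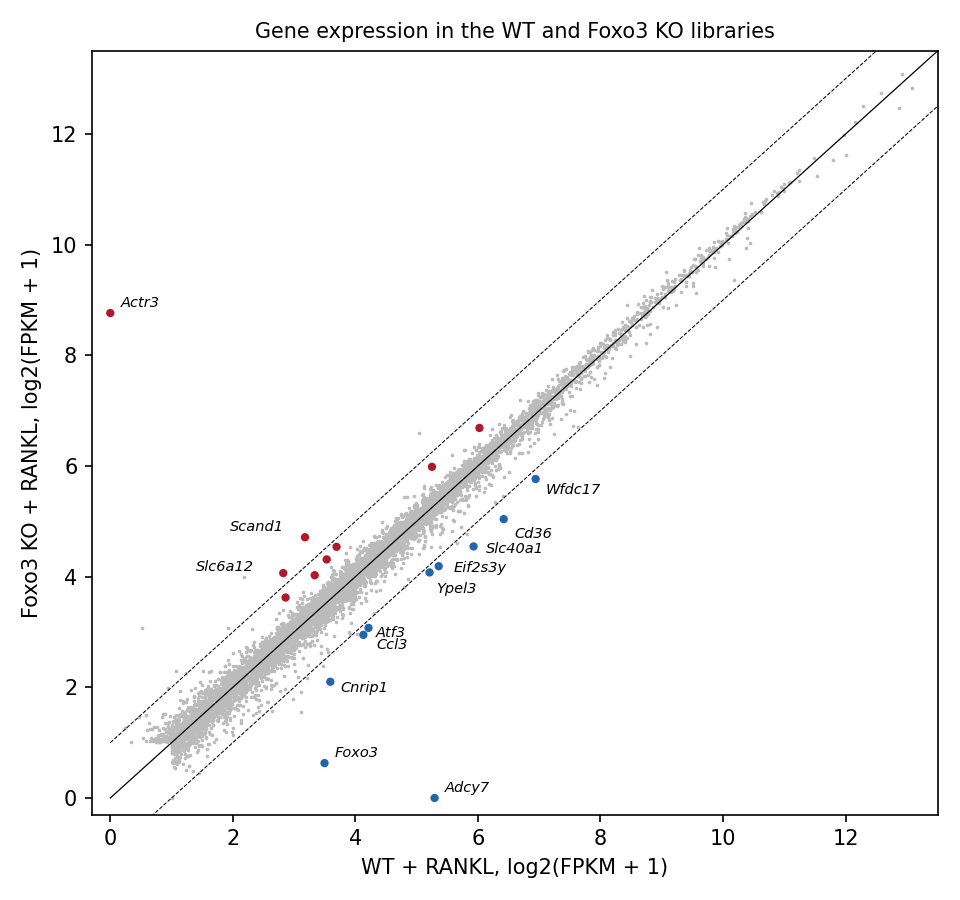
Each point is a measured gene, with log2(FPKM + 1) in the WT library on the x axis and in the Foxo3 KO library on the y axis. Dashed lines mark 2-fold, red and blue points are genes named in the text from those highest and lowest in the KO library, and those past 2-fold carry their symbols. Foxo3 lies far below the diagonal at 10.3 FPKM in the WT and 0.548 FPKM in the KO library, and Actr3 and Adcy7 lie on the axes because each was listed at 0 in 1 library.

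Macrophage markers were lower in the KO library in 29 of 31 measured cases, with a median log2 ratio of -0.32, and 0 of 10000 matched random lists had a median as low. Cd36 led the list. Fcgr3, an IgG receptor with similar copies, stood at 187.0 FPKM in the WT and 104.4 FPKM in the KO library, and the mannose receptor gene Mrc1 at 90.2 and 58.0 FPKM. Under both scalings 30 of the 31 were lower. Pf4, a platelet factor gene and the 1 measured member of the erythroid and megakaryocyte list, stood at 55.7 and 26.2 FPKM.

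The osteoclast lists did not stand apart from random lists. Of 34 measured members of the differentiation and resorption list 22 were higher, but only 17 under either scaling, and the median log2 ratio of 0.03 lay at percentile 15.35 of the random lists. The spread ran from Cd109 (56.4 FPKM in the WT and 42.2 FPKM in the KO library) to Pstpip2 (24.0 and 31.0 FPKM), with Car2, the carbonic anhydrase that supplies acid for resorption, at 172.0 and 215.3 FPKM, and Plekhm1, Itgb3 and Cd44 each at a log2 ratio of -0.28. Acp5, Ctsk and Mmp9, abundant resorption genes chosen after their values were seen, had log2 ratios of 0.16, 0.17 and 0.22. RANK signalling genes and osteoclast transcription factors were higher in 20 of 28 cases, 17 under either scaling, at percentile 82.79. Junb, whose exons overlap those of Prdx2, read 101.5 FPKM in the WT and 145.6 FPKM in the KO library, Relb 39.0 and 49.6 FPKM, and Tec 25.8 and 20.7 FPKM.

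Negative regulators of osteoclast differentiation were lower in 19 of 28 cases, with a median of -0.07 that 5 of 10000 random lists matched. Hmox1, haem oxygenase, stood at 197.3 FPKM in the WT and 103.5 FPKM in the KO library, and log2 ratios were -0.57 for the adaptor gene Dok2 and -0.50 for the inhibitory receptor gene Lilrb4, which has similar copies. FoxO target genes were lower in 19 of 28 cases (median -0.17, 0 of 10000 random lists as low), and among members at 10 FPKM or more the lowest were Ccnd1 (-1.09), which overlaps LTO1, the mitophagy kinase gene Pink1 (-0.62) and the catalase gene Cat (-0.58). The list mixes genes that FoxO factors activate with others they repress, and Ccnd1, cyclin D1, is known as repressed. Antioxidant genes were lower in 18 of 29 cases (median -0.15, 0 of 10000 as low), with Hmox1, Cat and Prdx4 (-0.44) farthest from 0. These 3 lists share members, among them Cat and Hmox1, and all were lower alongside the macrophage markers, whose median was -0.32.

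Interferon-stimulated genes were lower in 41 of 57 cases, with a median of -0.13, and 0 of 10000 random lists were as low. The 6 named members were all lower: Ifi204 (16.9 FPKM in the WT and 11.2 FPKM in the KO library), Oasl2 (14.4 and 10.6 FPKM), Sp100, Parp14, Oas2 and Trim30a, with log2 ratios from -0.55 to -0.29. None of the 57 differed by 2-fold. Isg15, chosen after its values were seen, had a log2 ratio of 0.24. Interferon ligand, receptor and sensing genes were not apart, with 10 of 19 lower and a percentile of 7.77, with Tlr7 (-0.52), Ikbke (-0.43) and Irf1 (0.29) farthest from 0. The median of the macrophage markers, -0.32, was lower than that of either list.

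Inflammatory cytokines and chemokines were lower in 11 of 17 cases (median -0.14, 4 of 10000 as low). Ccl3, Ccl6 (49.6 FPKM in the WT and 23.4 FPKM in the KO library) and Ccl4, chosen after its values were seen (7.63 and 1.94 FPKM), were over 2-fold lower, and Vegfa (18.7 and 25.7 FPKM) was higher. Ccl3, Ccl4 and Ccl6 lie with Wfdc17, also over 2-fold lower, between 83587882 and 83706268 on chromosome 11. They may not be independent of one another. The macrophage markers, at a median of -0.32, were lower alongside the cytokine and chemokine list too. MHC class II genes were higher in 10 of 12 cases (median 0.13, 127 of 10000 as high), with H2-DMb1 at 0.29 and Ifi30 at 0.24 and Ctss at -0.28, but the mean over members, 0.09, was not apart. MHC class I genes split 10 to 10, at percentile 8.30, with H2-L, which has near copies, at -0.57, Psmb9, which overlaps Tap1, at 0.26 and Psmb10 at 0.26.

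Oxidative phosphorylation genes were higher in the KO library in 41 of 41 cases, 40 under either scaling, with a median of 0.17 that 0 of 10000 random lists reached. Uqcrq, of respiratory complex III, read 344.1 FPKM in the WT and 480.4 FPKM in the KO library, and the cytochrome oxidase genes Cox8a and Cox6a1 had log2 ratios of 0.43 and 0.34. Cholesterol synthesis and uptake genes were higher in 19 of 20 cases, also under both scalings, with a median of 0.27 (0 of 10000 as high). Fdps stood at 54.1 and 76.9 FPKM, Mvd at 21.9 and 29.2 FPKM, and Cyp51, which overlaps Akap9, at 12.7 and 17.1 FPKM. Glycolysis genes were higher in 17 of 21 cases, 16 under either scaling (median 0.14, 12 of 10000 as high), with Aldoc at 0.35, Pfkp at 0.25 and Hk3 at -0.47, and the mean of 0.09 was not apart. Pfkp overlaps Pitrm1 and Hk3 overlaps Unc5a. None of these genes reached 2-fold. The medians of all 3 lists were higher in the library where 29 of 31 macrophage markers were lower, at a median of -0.32.

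Cell cycle genes were lower in 25 of 39 cases (median -0.08, 5 of 10000 as low), and the mean of -0.06 was not apart. Macrophage markers were lower in the same library, at a median of -0.32. Mcm6 and Mcm7, of the replicative helicase, had log2 ratios of -0.18 and -0.19, and Ube2c one of 0.24. Mcm7 overlaps Ap4m1 and Cops6, and Ube2c overlaps Tnnc2. V-ATPase and lysosome genes were higher in 22 of 36 cases, 19 under either scaling, with a median of 0.03 at percentile 8.08, while their mean was of opposite sign, -0.05, and apart on the low side. The lowest were Atp6v0a1 (-0.60), the lysosomal lipase gene Lipa (-0.53) and Ctsb (-0.42), which overlaps Fdft1.

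**Figure D2:**
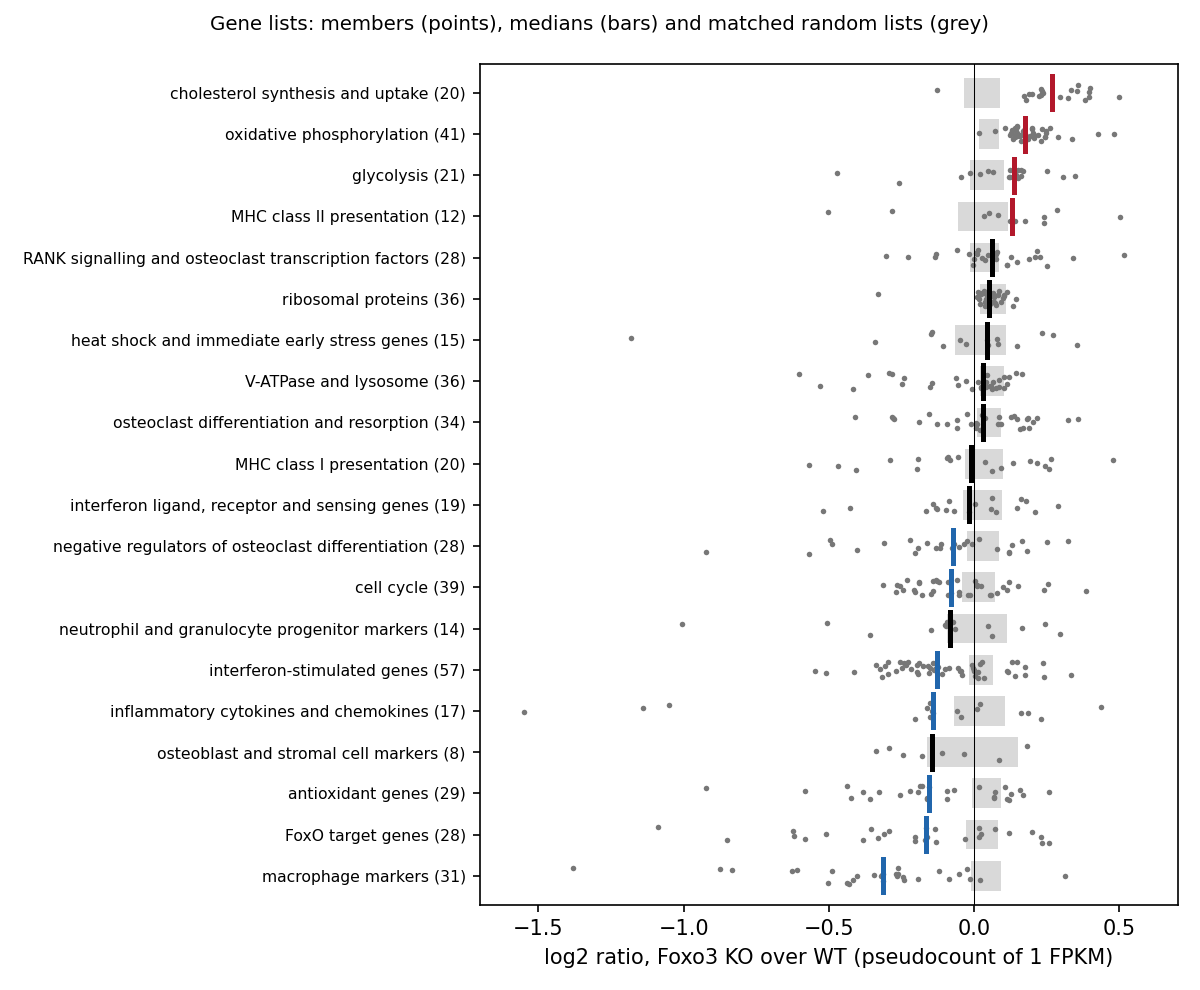
The x axis is the log2 ratio, KO over WT, and each row is 1 of the 20 gene lists given a percentile, with its number of measured members. Points are members, bars are list medians (red for higher and blue for lower than the central 95% of random lists, black for inside it), and grey boxes span that central 95%. Of these 20, the macrophage markers have the lowest median, -0.32, and cholesterol synthesis the highest, 0.27.

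No list of another cell type stood apart, though several held too few measured genes for a percentile. Neutrophil markers had a median of -0.08 at percentile 3.80, with S100a8 at 70.2 FPKM in the WT and 67.0 FPKM in the KO library, S100a9 at 53.6 and 55.4 FPKM, Chi3l3 at 11.6 and 13.9 FPKM, Ngp at a log2 ratio of -0.15 and Retnlg, chosen after its values were seen, listed at 1.01 FPKM and at 0. Stromal markers had a median of -0.14 over 8 genes at percentile 3.85, and none passed 3.35 FPKM, the level of Col1a1 in the WT library. The stromal list was apart only with a pseudocount of 5, and lay at percentile 19.80 with no minimum. The neutrophil list was apart only with no minimum, and lay at percentile 6.78 with a pseudocount of 5. Of the dendritic list 4 genes were measured, among them Bst2, also an interferon-stimulated gene, at 139.9 and 117.2 FPKM and Clec10a at 37.4 and 33.2 FPKM, while Cd4 and Cd5 alone of the T, NK and B cell list were measured, at 6.77 and 6.27 FPKM for the former and 6.27 and 6.17 FPKM for the latter. Prg2 was the 1 measured gene of the mast cell, basophil and eosinophil list, at 1.71 and 1.05 FPKM.

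Ribosomal protein genes were higher in 35 of 36 cases, 29 under either scaling, with a median of 0.05 at percentile 30.37 and Rpl13 and Rpl5, which overlaps Fam69a, both at 0.14. Heat shock and immediate early stress genes had a median of 0.04 at percentile 66.82 and a mean of opposite sign, -0.05, with Atf3 at -1.18, Asns at 0.35 and Ier2 at 0.27. The mitochondrially encoded transcripts were not analysed here. In all, 11 of the 20 lists given a percentile stood apart, 4 higher and 7 lower, against 1 that chance would give if genes were independent.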

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

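Leaving out genes listed at 0 and removing trends on transcript length and GC content were alternatives chosen after the data were seen. The directions of all 99 named genes held under both scalings. Both divide the KO values by 1.02, so they act nearly as a single alternative, and most named genes lay too far from 0 to change sign. Of 218 recomputed list values, most of them medians, 212 kept their side of the random-list bounds. Both scalings shift members and random lists nearly alike, and leaving out genes listed at 0 drops few genes. These settings could hardly move a list across a bound, so the share overstates how firmly the lists held. Sizes varied more. Over all settings the antioxidant list ran from -0.1810 to -0.0945. The cytokine and chemokine list ran from -0.2214, its mean over members, to -0.0577 with a pseudocount of 5. Both stayed apart in all 11 alternatives. With the mean over members, cell cycle (-0.0568), glycolysis (0.0871) and MHC class II genes (0.0905) were no longer apart, and V-ATPase and lysosome genes (-0.0533) were apart on the low side. Stromal markers were apart with a pseudocount of 5 (-0.0719) and neutrophil markers with no minimum (-0.0833, by a list percentile of 1.82). The cause was not tested for these lists. The count of higher genes was 5 with a pseudocount of 5, 5 with a minimum of 10 FPKM, 41 at 1.5-fold and 2 at 4-fold. The count of lower genes was 39 with a pseudocount of 0.25, 6 with a pseudocount of 5, 94 at 1.5-fold and 2 at 4-fold. These follow from the construction of the thresholds, the filter and the pseudocount, as do the log2 ratios of Foxo3, -3.72 with a pseudocount of 0.25 and -1.46 with 5. Of 392 recomputed log2 ratios of other named genes, 23 moved, all with another pseudocount. The bound was the spread of genes of like expression or, for named genes that were not measured, such as Epor, Kit and Ppbp, a fixed size. Both scalings gave 11 higher and 22 lower genes. The alternative with a counting interval was not run, since it needs counts. No paired analysis was possible because each group holds 1 library, which also rules out leaving 1 out. Depth limits low genes most, and the WT library is the shallower by the estimate from low genes.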

Other observations

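The tests on length and GC content were set out before their results were seen. All others here were chosen, or their bounds set, after at least part of the values had been seen: those on the zeros of Actr3 and Adcy7, on depth, on osteoclast differentiation, on the zinc finger genes, on genes near Foxo3 and on iron genes.

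Of the sex-linked transcripts, the Y-linked Eif2s3y stood at 40.1 FPKM in the WT and 17.2 FPKM in the KO library, Ddx3y at 21.5 and 18.1 FPKM and Kdm5d at 4.94 and 4.11 FPKM. Uty, also on the Y chromosome, had a log2 ratio of 0.11, against -1.17, -0.24 and -0.22 for the others.

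Actr3 and Adcy7 were the 2 genes at 10 FPKM or more in 1 library and listed at 0 in the other. If estimates had failed, the exact zeros would stand apart from partial losses. Other than Foxo3, 0 genes at that level lay above 0 and below 20% of their value in the other library, and the next lowest stood at 23.8%. Few genes differed strongly in any case, so this band could be empty under either explanation. The other 6 Arp2/3 subunits looked at had log2 ratios from -0.14 to 0.04. A failed estimate is a candidate explanation, and a true absence was not excluded by these values.

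The macrophage markers were lower and the oxidative phosphorylation genes higher in the KO library, and this may be biological or technical. Removing trends on transcript length and GC content left medians of -0.3092 and 0.1524, both still beyond 10000 random lists, which argues against those trends as the whole cause. The 17 markers at 50 FPKM or more had a median of -0.3206, with 16 lower. The fall was thus not confined to genes of few reads. These markers are part of the same list, so they give no independent evidence on depth as the cause. A culture further along towards osteoclasts cannot be told apart from other explanations: the osteoclast list lay at percentile 15.35, but its members went both ways. Differences between the animals or cultures, and the genotype itself, stay open because each group is 1 library.

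Near the end of chromosome 2, from 175061549 to 178078476, all 7 measured zinc finger gene models were higher in the KO library by 0.5 or more (log2), with Etohi1 at 0.436 FPKM in the WT and 7.46 FPKM in the KO library and Gm14295 at 3.55 and 14.9 FPKM, a pattern chosen after its values were seen. Their summed FPKM was 7.07 in the WT and 31.7 in the KO library, a log2 ratio of 2.16 without a pseudocount. This does not decide whether reads moved between copies, an explanation narrowed from reads shared between copies after the sum was seen: 6 of the 7 were under 1 FPKM in the WT library and count as measured through their KO value, and 8 of the 29 coding models with Gm or Zfp symbols annotated in that stretch had a value to use here. The 9 other measured genes looked at, none of which lies within the stretch, flank it between 174076308 and 178424428 and had a median of -0.01. Reads moved or spread between copies, and a difference in strain or parentage between the animals, stay open. Whether DNA of another strain came along with the Foxo3 mutation cannot be told: within 20 Mb of Foxo3, 1 of 96 measured genes (1.04%, exact binomial 95% interval 0.026 to 5.67%) differed by 0.5 or more, against 2.15% elsewhere. The interval lies below 6.45%, the size of 3 times the share elsewhere that the test had set for this cause, but it covers smaller excesses, and such DNA need not alter expression.

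Hmox1 and Slc40a1, which act on haem and iron, were lower in the KO library, as were the ferritin genes Fth1 (-0.38) and Ftl1 (-0.25), the biliverdin reductase gene Blvrb (-0.49) and Spic (-0.13), a transcription factor gene. The macrophage markers were lower in the same library, at a median of -0.32. The hypothesis that iron-handling genes may have shifted as a group was tested on 29 other haem and iron genes. They were listed once the first 6 had been noticed and without them. Their median was 0.0168, at percentile 28.20 of random lists, and not below the bound of -0.0217 set for a shift of the group. Of the 29, 14 were lower, with members on both sides, from Lrp1 (-0.55) to Steap4 (0.61). These 29 thus did not fall as a group in these libraries, but the test does not decide whether some of them shifted. Steap4 was left out of an earlier form of this list after its value was seen, and is included here.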
